A study of Mus musculus with 10 samples.

How the data were processed

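Total RNA from cultured mouse lung fibroblasts was hybridised as biotin-labelled cRNA to Affymetrix Mouse430_2 arrays, a 1-colour platform on which each transcript is read by a probe set of short oligonucleotides. There were 10 arrays, 5 of fibroblasts from normal lung and 5 of carcinoma-associated fibroblasts (CAF). Per the labels' protocols, the cells were isolated from mouse lungs, expanded for 10 to 14 days in medium with 10% serum, replated on 10 cm dishes and grown overnight, and 6 ug of total RNA went into each labelling. The titles call the arrays of a group biological replicates, and the groups and replicate numbers were taken from the titles. The description fields repeat replicate number 1 on the arrays and were not used for numbering.

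The authors' deposited table holds log2 expression values, 1 column per array. Per the submitters' processing notes, the values were made with the robust multi-array average method (RMA) in Affymetrix Expression Console, and limma was among the tools, with no version given in the sources used here. RMA subtracts background, quantile-normalises the probes and summarises each probe set on a log2 scale, so array-wide differences in brightness are largely removed and differences between groups are relative to the other probe sets of the same array. RMA gives no detection call, so a low value may be background and no gene is called absent. Differences of dim probe sets are less certain in size than those of bright ones. The deposited log2 values ran from 3.98 to 15.5. The array medians and spreads were close to each other, as in values normalised before deposit, though both still differed slightly between the groups.

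The table has 45101 probe sets, of which 64 control probe sets were left out. Gene names came from a probe-to-gene table of the platform, with symbols updated through Entrez gene numbers to the names in the gene table of mouse assembly GRCm38.p6. That table was used for names only, and no coordinates are given. Of the 45037 other probe sets, 34945 had 1 gene symbol, 932 had several and 9160 were not listed. The Entrez number of 34741 of the single-gene probe sets was found in the gene table, and the others kept the symbol of the platform table. Each gene was represented by the single-gene probe set with the highest mean over all 10 arrays, which gave 18193 genes, 9011 of them with more than 1 probe set. All array columns of the table were used.

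Genes were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with the default prior), with group as the only term and no further normalisation. P-values were adjusted over all genes with the Benjamini-Hochberg method, and a gene was called at an adjusted p under 0.05. Differences are CAF minus normal on the log2 scale, with the moderated standard error, and every adjusted p printed for a gene is from this limma fit unless another test is named. The precision of these values is limited by the number of arrays, 5 in each group.

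A total of 43 gene lists were fixed, 12 of them markers of other cell types that a lung fibroblast culture could hold (macrophages and monocytes, neutrophils, lymphocytes, endothelium, epithelium, alveolar and airway epithelium, pericytes and vascular smooth muscle, mesothelium, Schwann and neural cells, skeletal muscle, cartilage and erythroid cells) and 1 a control list of ribosomal proteins. Of 754 list members, 692 (91.8%) were matched to a tested gene. Each list was tested with camera (competitive, preset correlation 0.01), with camera at an estimated correlation, and with fry (self-contained: do the members move, on balance, one way), each adjusted over the lists. An exact 2-sided permutation test of the mean of each list per array was added after the data had been seen; its smallest possible p is 0.00794. A list's call is that of camera with the preset correlation, and its direction in the comparisons of settings is camera's. Counts adjusted over the list alone used the members' own p-values.

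Genes were named by a fixed rule. It took the 10 largest increases and the 10 largest decreases among called genes whose 5 values did not overlap between groups, passing over clone names, predicted genes and sex-linked genes. It also took the fibroblast genes Acta2, Fap, Pdgfra, Pdgfrb, S100a4, Vim, Col1a1, Il6, Clcf1, Cxcl12 and Tgfb1, the 3 members with the smallest p in each described list with the best member in the other direction, and the 3 brightest members of each list of another cell type. Il6 and Clcf1 were put in because they are known from published work on lung CAF, possibly on these samples, so their direction is not independent evidence. The rule, the lists, the test and the alternatives, except those named below as added, were fixed before the data were examined.

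The label codes of the normal arrays begin with 1 of 2 prefixes, vs for replicates 1 to 3 and ls for replicates 4 and 5, and all CAF arrays have ls. The labels do not say what the prefixes mean; they were treated as a possible batch, and a model with 3 groups gave the CAF difference against each kind of normal array. Replicate numbers are shared between the groups. Nothing in the labels says that a number marks a shared animal, and same-numbered arrays did not deviate together, so the arrays were not paired.

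The alternatives were a variance prior with intensity trend and robust estimation, filters that left out genes with a mean under 5 or under 7, quantile normalisation and median centring of the arrays, other ways to represent a gene (mean of its probe sets, no probe sets with an _x_at or _s_at suffix, all probe sets tested singly), array weights, an exact Wilcoxon test, the replicate number as a block, the label prefix as a term, the ls arrays alone, the level of Y-linked genes as a covariate, and each array left out in turn. The level of macrophage markers, the level of the cell cycle list and the exact permutation of list means were added after the data had been seen, as were linear models of the inflammatory list mean with the prefix and these levels together. The fit was tested on simulated data for the same 18193 genes, with 100 genes changed 2-fold and 100 changed 4-fold. It recovered 79% and 90% of them, with 12 false calls among 181. The simulated noise was independent between genes, with the same SD in both groups and no effect of the label prefix. The real values have correlated genes and a larger spread in the normal group. These rates are therefore no estimate of power or false calls for the real comparison. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.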

Results

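Gene expression was measured in cultured fibroblasts from normal mouse lung and in carcinoma-associated fibroblasts (CAF), the fibroblasts that populate a tumour, with 5 arrays per group. Values are RMA log2 expression, and 18193 genes were tested. The array medians over all probe sets lay between 6.76 and 6.80 in the normal group and between 6.73 and 6.74 in CAF. The SD over probe sets was 2.34 to 2.39 on normal and 2.41 to 2.44 on CAF arrays. The upper quartile was 9.05 to 9.13 on normal and 9.22 to 9.30 on CAF arrays. The groups thus did not overlap in any of these measures. Across probe sets, the median Pearson correlation between arrays was 0.959 within the normal group (0.926 to 0.989), 0.985 within CAF (0.977 to 0.990) and 0.969 between groups (0.940 to 0.991). The normal cultures differed more from each other than the CAF cultures did: 12930 genes (71.1%) had the larger SD in the normal group, with a median SD of 0.21 against 0.14 on the log2 scale. The normal arrays carry both label prefixes, vs and ls, and the CAF arrays only ls. This spread cannot be told apart from a difference between the prefixes. Y-linked genes were bright on 3 of 5 arrays in each group, and Xist on the other arrays.

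The comparison of CAF with normal lung fibroblasts asks which genes are expressed differently after both had been isolated and grown in culture. The genes with the largest increases in CAF included a set of secreted inflammatory signals. Il1a, a cytokine that starts inflammatory responses, rose 11.0-fold, from a log2 level of 7.96 ± 1.37 to 11.42 ± 0.68 (SD, n = 5 per group; limma adjusted p = 0.0483). Csf3, the growth factor of granulocytes, rose 7.69-fold, from 7.50 ± 0.43 to 10.45 ± 0.65 (adjusted p = 0.0212), and Lif, a cytokine of the interleukin-6 family, rose 5.11-fold, from 9.17 ± 0.80 to 11.53 ± 0.44 (adjusted p = 0.0394). Clcf1, a cardiotrophin-like cytokine of the same family, rose 2.27-fold, from 9.11 ± 0.38 to 10.29 ± 0.29 (adjusted p = 0.0483), and its 3 probe sets differed by 1.02 to 1.22 on the log2 scale. Clcf1 is not among the 10 largest increases. It was named beforehand from published work, possibly on these samples, so its direction is not independent evidence. The values of the 5 CAF arrays did not overlap those of the 5 normal arrays for any of these genes. That is no separate support, since it was a condition for naming Il1a, Csf3 and Lif and held for all 137 called genes.

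**Figure D1:**
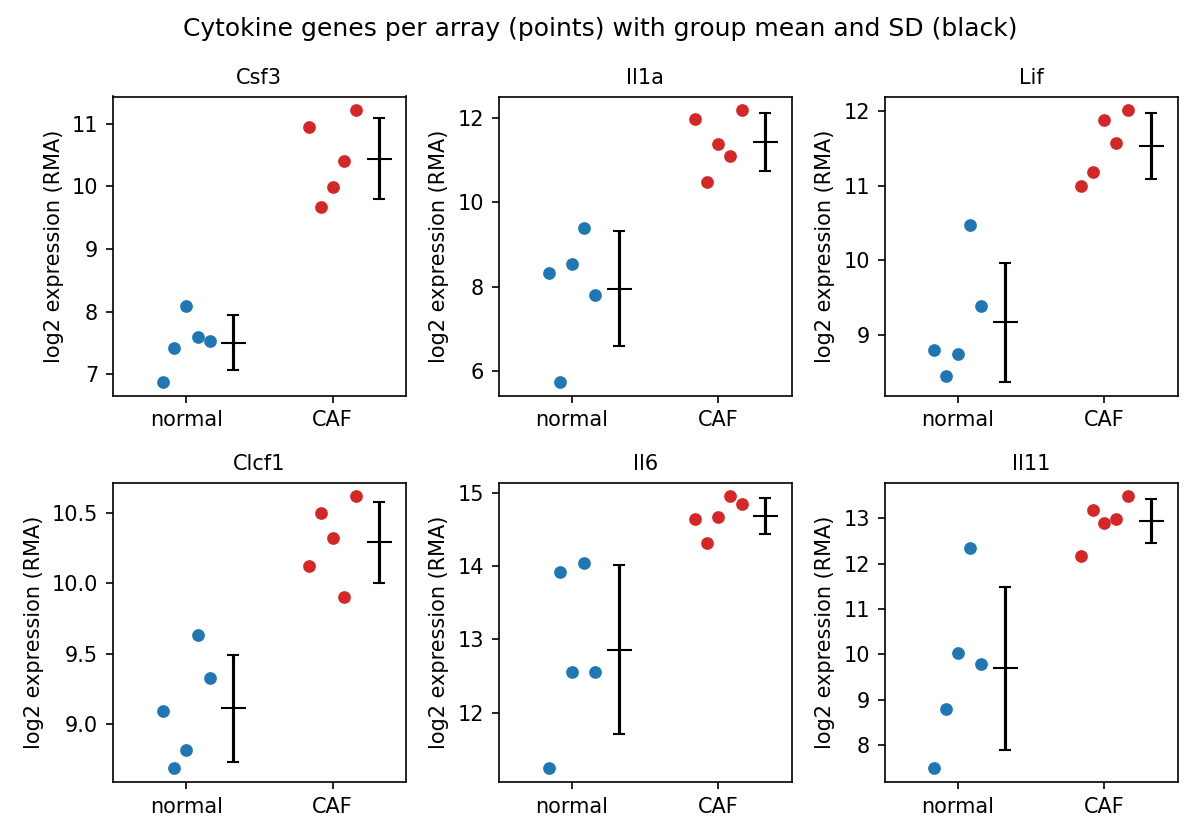
Log2 expression (RMA, y axis) of 6 cytokine genes on each of the 5 normal (blue) and 5 CAF (red) arrays, with the group mean and SD in black; each panel has its own y axis. Csf3, Il1a, Lif and Clcf1 passed the test, with adjusted p-values of 0.0212, 0.0483, 0.0394 and 0.0483, and Il6 and Il11 did not, at 0.0860 and 0.0684.

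Other genes with large increases act at the cell surface, in the cytoskeleton or in signalling. Sorbs2, an adaptor of actin-based contacts, was higher by 2.89 ± 0.46 (log2 difference ± SE), and Kcnk10, a background potassium channel, by 2.77 ± 0.49. Rgs16, which shortens G protein signalling, was higher by 2.73 ± 0.43, Septin4, a cytoskeletal GTPase, by 2.46 ± 0.34, and Dkk2, a secreted modulator of WNT signalling, by 2.44 ± 0.39. Olr1, a scavenger receptor for oxidised lipoprotein, was higher by 2.37 ± 0.33, and Sprr2h, of a family known from epidermal differentiation, by 2.30 ± 0.42. Against the ls and the vs normal arrays, Sorbs2 differed by 3.21 and 2.68, Kcnk10 by 2.14 and 3.19, Rgs16 by 1.91 and 3.28, Septin4 by 2.47 and 2.45, Dkk2 by 2.14 and 2.64, Olr1 by 2.16 and 2.50 and Sprr2h by 1.86 and 2.60. The adjusted p-values of these 7 genes lay between 0.0271 and 0.0484. The probe set of Sprr2h has the _s_at suffix given to probes shared by related transcripts, which does not separate the members of its family. Of the 3 dimmer probe sets of Sorbs2, 1 was higher by 0.84 and the others had differences of -0.09 and -0.12, and the dimmer probe set of Kcnk10 was higher by 0.78 ± 0.13. The other probe sets of Rgs16, Septin4 and Lif were higher by 1.65 or more.

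The genes with the largest decreases in CAF have varied roles. Slc43a3, a purine base transporter, was 2.50-fold higher in normal fibroblasts (log2 difference -1.32 ± 0.24, adjusted p = 0.0484). Cdkn1b, a cyclin-dependent kinase inhibitor that holds back cell division, was 2.49-fold higher in normal fibroblasts (-1.32 ± 0.24, adjusted p = 0.0484). Its dimmer probe set differed by -0.32 ± 0.18. The apolipoprotein gene Apoc1 fell by 0.97 on the log2 scale, the pregnancy-specific glycoprotein gene Psg28 by 0.91 and Hdgfl3, of the hepatoma-derived growth factor family, by 0.89. The zinc finger transcription factor Maz, the microtubule-linker gene Clip4, the linker histone H1f10, the serpin Serpinb6e and the F-box gene Fbxw22 had differences of -0.63 to -0.54. Serpinb6e was read by a single probe set with the _x_at suffix, given to probes that may also bind other transcripts. Against the ls and the vs normal arrays, Slc43a3 differed by -0.95 and -1.57 and Cdkn1b by -1.04 and -1.50. Adjusted p-values of the 8 genes from Apoc1 to Fbxw22 ran from 0.0271 to 0.0483.

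A total of 137 genes differed between CAF and normal lung fibroblasts, 102 higher and 35 lower in CAF, and 41 of them differed at least 2-fold, 38 higher and 3 lower. The median log2 difference was 0.82 among the genes that rose and -0.50 among those that fell, and the median over all genes was -0.04. After quantile normalisation of the same values the test called 90 genes, 41 higher and 49 lower, so that increases outnumber decreases only under some scalings. The genes called lower include 2 chemosensory receptor genes, which fibroblasts are not known to use, Vmn1r148 (-0.50 ± 0.09) and Olfr701 (-0.33 ± 0.06). The 5 CAF values and the 5 normal values did not overlap in all 137 genes, and over all genes this held for 540 higher and 762 lower, 7.16% of genes against 0.794% by chance. The calls lay close to the threshold: 4054 genes had an unadjusted p under 0.05, against 910 by chance, and 1163 had an adjusted p up to 0.1. The count depended on single arrays. Without normal replicate 1 it was 24, without normal replicate 4 it was 63 and without normal replicate 5 it was 46. Limma called 0 genes without normal replicate 3 or CAF replicate 1, 3 or 5, with 3852, 3378, 3538 and 3003 genes at an unadjusted p under 0.05, and 1 gene without CAF replicate 4. The count of 2-fold differences was 9 without normal replicate 1, 63 without normal replicate 2, 19 without normal replicate 5, 1 without CAF replicate 4 and 0 without normal replicate 3 or CAF replicate 1, 3 or 5. The exact Wilcoxon test on all arrays gave 0 calls (3184 genes at an unadjusted p under 0.05, lowest adjusted p 0.111). The 137 genes already have its smallest possible p, 0.00794, so it says nothing about their stability. Against the 2 normal arrays with label prefix ls alone, the differences were 2.82 ± 0.80 for Il1a, 2.88 ± 0.44 for Csf3, 1.60 ± 0.34 for Lif and 0.81 ± 0.20 for Clcf1; against the 3 with prefix vs they were 3.89 ± 0.70, 2.98 ± 0.39, 2.86 ± 0.30 and 1.43 ± 0.18. With the prefix as a term in the model, limma called 0 genes (2649 at an unadjusted p under 0.05, lowest adjusted p 0.292).

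**Figure D2:**
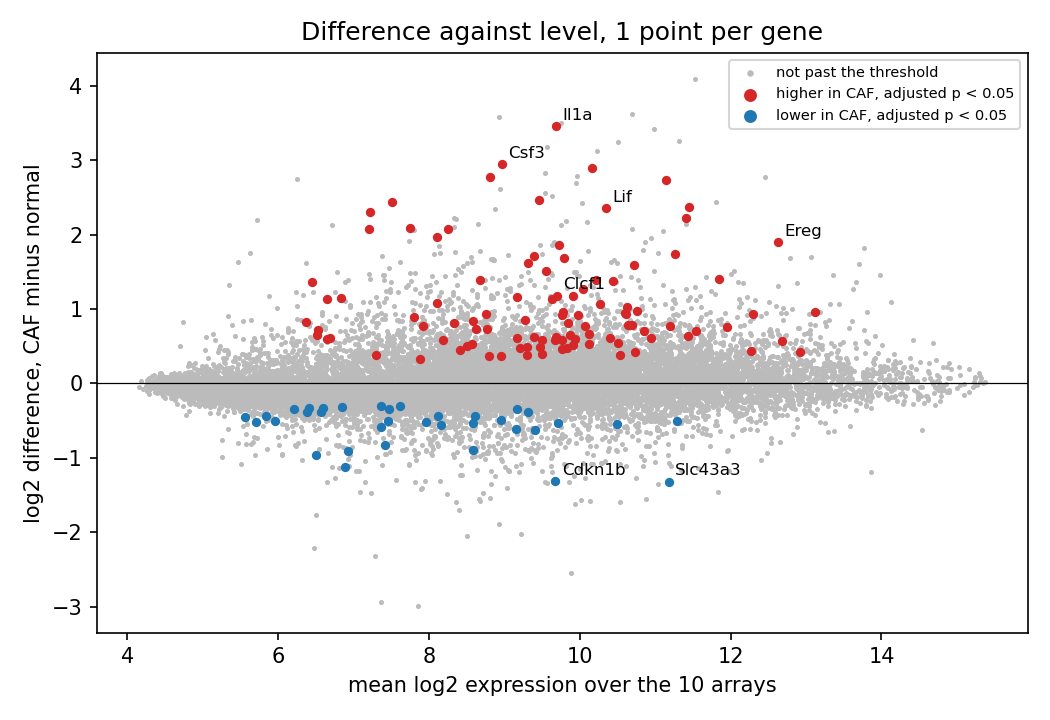
Log2 difference of CAF minus normal (y axis) against the mean log2 expression over the 10 arrays (x axis), 1 point per gene, with the 102 genes called higher in CAF in red, the 35 called lower in blue and the others in grey. Increases reach 3.46 (Il1a) and decreases -1.32 (Slc43a3), and the median level was 9.70 for the genes that rose and 7.47 for those that fell.

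Inflammatory cytokines and chemokines were higher in CAF as a list. Of 37 members measured, 3 rose (Csf3, Lif and Il1a), 0 fell and 34 did not pass the test over all genes; adjusted over the list alone, 18 rose and 0 fell. The median log2 difference of the members was 1.06, and 28 were positive and 9 negative. The list mean per array was 10.89 ± 0.34 in CAF and 9.66 ± 0.58 in normal fibroblasts (SD, n = 5), and the lowest CAF array, at 10.49, lay above the highest normal array, at 10.34. Camera called the list (adjusted p = 4.35e-08); the call was lost with an adjusted p = 0.510 with an estimated correlation, and fry gave an adjusted p of 0.0819. Over its 28 alternatives the list was called in 25, with adjusted p-values of 4.48e-12 to 0.510 and medians of 0.87 to 1.34. The 25 calls all came from camera with the preset correlation of 0.01, whereas the estimated correlation of the members was 0.230. The alternatives without a call were camera with the estimated correlation, fry and the exact permutation. The count of 25 therefore says nothing about that preset. The exact permutation p of the list means was 0.00794, the smallest that 5 against 5 arrays can give, and 0.0853 after adjustment over the lists. Among members that did not pass, Ccl2, which attracts monocytes, had a difference of 1.61 ± 0.41 (adjusted p = 0.0829), Cxcl1, which attracts neutrophils, 2.77 ± 0.79 (adjusted p = 0.0963), and Ptgs2, the inducible cyclooxygenase, 1.36 ± 0.47 (adjusted p = 0.139); these 3 were chosen after their values were seen. Cxcl9, an interferon-induced chemokine, had -0.21 ± 0.09 (adjusted p = 0.232). The list mean differed by 1.13 between CAF and the ls normal arrays and by 1.30 between CAF and the vs normal arrays. Macrophage markers, which are read on the same arrays, had a list mean of 11.63 ± 0.86 in CAF and 11.16 ± 1.34 in normal fibroblasts.

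The interleukin-6 family list, cytokines that signal through the shared receptor chain Il6st with their receptors and kinases, had 15 members measured, of which 2 rose (Lif and Clcf1), 0 fell and 13 did not pass. Adjusted over the list alone, 4 rose and 1 fell, which is not independent evidence, since Il6 and Clcf1 may have been chosen by the study on these samples. Il6 itself had a difference of 1.82 ± 0.48 (3.54-fold, adjusted p = 0.0860), with no overlap between the groups, and Il11, a cytokine of the family produced by fibroblasts, had 3.25 ± 0.75 (adjusted p = 0.0684). Cntfr, a receptor of the family, had -0.36 ± 0.11 (adjusted p = 0.106). The median of the list was 0.36 (0.29 over the 13 members other than Il6 and Clcf1), and 3 members are also in the inflammatory list. Camera did not call it (adjusted p = 0.0619, and adjusted p = 0.608 with an estimated correlation), but did without normal replicate 1 (median 0.35), without normal replicate 2 (0.56) and without CAF replicate 3 (0.38). The median was 0.16 without normal replicate 3 and 0.24 without CAF replicate 4. Over its 28 alternatives the adjusted p ran from 0.0160 to 0.608. Against the ls normal arrays Il6 differed by 1.39 ± 0.63 and Il11 by 1.88 ± 0.77, and against the vs normal arrays by 2.11 ± 0.55 and 4.17 ± 0.68.

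**Figure D3:**
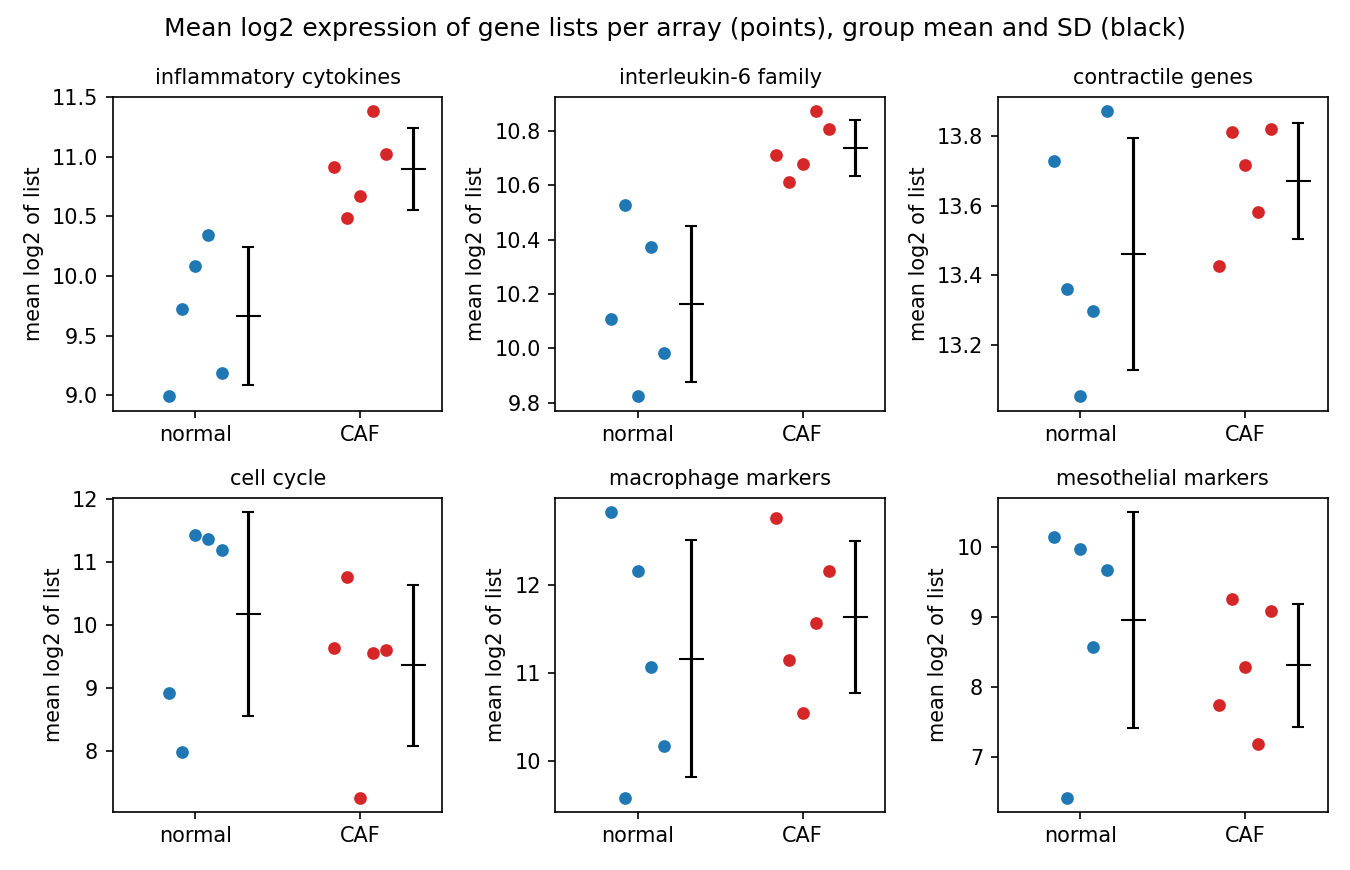
Mean log2 expression (y axis) of 6 gene lists on each of the 5 normal (blue) and 5 CAF (red) arrays, with group mean and SD in black; each panel has its own y axis. The inflammatory list runs from 8.99 to 10.34 in normal and from 10.49 to 11.38 in CAF arrays, while the groups overlap in the contractile, cell cycle, macrophage and mesothelial lists.

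Secreted growth factors and WNT pathway genes held single genes that changed. Of 32 growth factors, 1 rose, Ereg, a ligand of the epidermal growth factor receptor (1.89 ± 0.35, 3.72-fold, adjusted p = 0.0484; 1.09 against the ls and 2.43 against the vs normal arrays), 0 fell and 31 did not pass; adjusted over the list alone, 2 rose. Pdgfa, a platelet-derived growth factor, had 0.80 ± 0.16 (adjusted p = 0.0529), and Ptn, pleiotrophin, had -0.22 ± 0.07 (adjusted p = 0.119), with its dimmer probe sets at 0.14 ± 0.38 and 0.36 ± 0.74. The median of the list was 0.14 (camera adjusted p = 0.163); it was called without normal replicate 1 (0.26) and without normal replicate 2 (0.26), and the median was 0.057 without normal replicate 4. Of 28 WNT pathway genes, Dkk2 rose, 0 fell and 27 did not pass, also 1 adjusted over the list alone, with a median of -0.07 (adjusted p = 0.800). The ligand Wnt10b had -0.26 ± 0.07 (adjusted p = 0.0933) and the receptor Fzd7 0.54 ± 0.17 (adjusted p = 0.121). With 1 probe set per gene, 0 of the 6 IGF binding proteins passed over all genes in limma, and 1 rose and 1 fell adjusted over the list alone. Igfbp5 had 4.09 ± 1.07 (adjusted p = 0.0860), Igfbp3 -2.55 ± 0.88 (adjusted p = 0.138) and Igfbp6 -1.07 ± 0.45 (adjusted p = 0.196), and the list had a median of 0.26 (camera adjusted p = 0.771; 0.020 to 0.48 without 1 array). The dimmer probe set of Igfbp5 was higher by 1.86 ± 0.34, with an adjusted p of 0.0429 when all probe sets are tested singly. Against the ls and the vs normal arrays Igfbp5 differed by 2.96 ± 1.38 and 4.83 ± 1.20 and Igfbp3 by -1.77 ± 1.16 and -3.07 ± 1.01.

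Genes used in the literature to mark CAF or activated fibroblasts did not pass the test. Of 16 such markers measured, 0 passed over all genes or adjusted over the list alone, and their median difference was 0.04 with a mean of -0.03 (camera adjusted p = 0.71; medians of -0.046 to 0.12 without 1 array). Acta2, smooth muscle actin, was near the top of the scale in both groups, at 15.25 ± 0.21 in normal and 15.35 ± 0.07 in CAF arrays (difference 0.10 ± 0.10, adjusted p = 0.583), and its dimmer probe sets had 0.63 ± 0.41 and 0.19 ± 0.26. Vim, the filament protein vimentin, had 0.08 ± 0.10 (adjusted p = 0.656) and S100a4, a calcium-binding protein of fibroblasts, -0.21 ± 0.20 (adjusted p = 0.559). Fap, a membrane protease, -0.85 ± 0.70 (adjusted p = 0.492), Pdgfra -0.54 ± 0.55 (adjusted p = 0.592) and Pdgfrb, both receptors of platelet-derived growth factor, 0.43 ± 0.51 (adjusted p = 0.648). Fap differed by -1.96 ± 0.78 against the ls and by -0.11 ± 0.68 against the vs normal arrays. The chemokine gene Cxcl12 had -0.29 ± 0.56 (adjusted p = 0.783). The members with the smallest p were Tnc, the matrix protein tenascin (1.45 ± 0.50, adjusted p = 0.138), Col11a1, a minor fibrillar collagen (-1.11 ± 0.43, adjusted p = 0.174), and Cav1, caveolin (-0.74 ± 0.38, adjusted p = 0.278).

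Contractile genes and TGF-beta pathway genes, which mark myofibroblasts and their main inducer, had small median differences. Of 19 contractile genes 0 passed over all genes or adjusted over the list alone, with a median of 0.14 and 16 positive. Actg2, an enteric smooth muscle actin, had 1.07 ± 0.35 (adjusted p = 0.129), Myh11, smooth muscle myosin, 1.12 ± 0.41 (adjusted p = 0.152), and Smtn, smoothelin, -0.53 ± 0.27 (adjusted p = 0.275). Camera called the contractile list (adjusted p = 0.0417), which was lost at adjusted p = 0.803 with an estimated correlation (0.00432 to 0.803 over its alternatives). The list mean differed by 0.09 between CAF and the ls normal arrays and by 0.29 between CAF and the vs normal arrays. Of 23 TGF-beta pathway genes 0 passed over all genes or adjusted over the list alone, with a median of 0.20 and 18 positive. The call (camera adjusted p = 0.0238) was lost at adjusted p = 0.510 with an estimated correlation (0.00244 to 0.510 over its alternatives), and the list mean differed by 0.22 against each kind of normal array. Skil, a feedback repressor of the pathway, had 0.33 ± 0.10 (adjusted p = 0.101; dimmer probe set 0.62 ± 0.23) and Inhba, an activin subunit, 1.31 ± 0.39 (adjusted p = 0.107). Tgfbr1, a receptor, had 0.59 ± 0.19 (adjusted p = 0.124; dimmer probe sets 0.98 ± 0.26 and 0.90 ± 0.25), Id3 -0.23 ± 0.11 (adjusted p = 0.237) and the ligand Tgfb1 itself 0.35 ± 0.25 (adjusted p = 0.434). The dimmer probe sets of Inhba and Tgfb1 had the opposite sign. Inhba differed by 0.33 ± 0.21 against the ls and by 1.96 ± 0.18 against the vs normal arrays. The contractile call was also lost without normal replicate 2 (median 0.13), 3 (0.06) or 4 (0.08) and without CAF replicate 2 (0.11), 3 (0.14), 4 (0.15) or 5 (0.12), and the median was 0.21 without normal replicate 1 and 0.24 without normal replicate 5. The TGF-beta call was lost without normal replicate 3 (0.11).

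Extracellular matrix genes did not pass the test in either direction. Of 21 collagens 0 passed over all genes and 1 fell adjusted over the list alone (Col8a2, -0.39 ± 0.09, adjusted p over all genes = 0.0635), with a median of -0.15 (camera adjusted p = 0.291). Col1a1, the main fibrillar collagen, had -0.28 ± 0.25 (adjusted p = 0.529; dimmer probe set -0.63 ± 0.18), Col6a1 -0.91 ± 0.36 (adjusted p = 0.182) and Col12a1 1.13 ± 0.60 (adjusted p = 0.295), with 1 of its dimmer probe sets at -0.08 ± 0.08. Without normal replicate 3 the collagens were called lower (median -0.39), and without CAF replicate 5 the median was -0.049. Of 17 genes of collagen processing 0 passed over all genes or adjusted over the list alone, with a median of -0.01 and camera pointing up (adjusted p = 0.892). The collagen chaperone Serpinh1 had -0.28 ± 0.10, the lysyl hydroxylase Plod2 -0.33 ± 0.15 and the prolyl hydroxylase P3h2 0.28 ± 0.14. Of 30 matrix glycoproteins and proteoglycans 0 passed over all genes and 1 fell adjusted over the list alone (Eln, elastin, -0.46 ± 0.10), with a median of 0.05 (adjusted p = 0.609). Ogn, osteoglycin, had -2.05 ± 0.65 (adjusted p = 0.121). Of 25 matrix proteases and inhibitors 0 passed over all genes or adjusted over the list alone, with a median of -0.03, a mean of 0.13 and camera pointing up (adjusted p = 0.337). Among these the collagenase Mmp13 had 1.66 ± 0.51, the urokinase gene Plau 0.84 ± 0.31, the inhibitor Timp1 0.23 ± 0.08 and the gelatinase Mmp2 -0.53 ± 0.28, with adjusted p-values of 0.111 to 0.286. Without 1 array the medians ran from -0.13 to 0.19 (collagen processing), -0.048 to 0.15 (glycoproteins) and -0.11 to 0.18 (proteases).

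Lists of signalling response genes were called by camera with no member past the test over all genes. Of 15 genes of RAS-MAPK feedback 2 rose adjusted over the list alone. Ier3, an early response gene that limits cell death, had 1.26 ± 0.24 (adjusted p = 0.0508), Phlda1 0.65 ± 0.18 (adjusted p = 0.0930), Fosl1, a subunit of the AP-1 transcription factor, 1.32 ± 0.47 (adjusted p = 0.143). Fosl1 differed by 0.53 ± 0.51 against the ls and by 1.85 ± 0.44 against the vs normal arrays. The inhibitor Spred1 had -0.13 ± 0.15 (adjusted p = 0.641), and 2 of its dimmer probe sets had the opposite sign. The list median was 0.45 (camera adjusted p = 0.00728, lost at adjusted p = 0.510 with an estimated correlation). Over its alternatives the adjusted p ran from 0.000947 to 0.510, and without normal replicate 2 the median was 0.24. The list mean differed by 0.19 against the ls and by 0.67 against the vs normal arrays. Of 14 immediate early genes, transcription factors induced within minutes of a stimulus, 1 rose and 1 fell adjusted over the list alone. Jun had 0.45 ± 0.13 (adjusted p = 0.101), the nuclear receptor Nr4a1 1.13 ± 0.38 (adjusted p = 0.131) and Egr3 -0.28 ± 0.06 (adjusted p = 0.0668). The dimmer probe set of Egr3 had 0.71 ± 0.63, and over its 26 alternatives Egr3 ran from -0.35 to 0.21. The median was 0.46 (camera adjusted p = 0.0160, lost at adjusted p = 0.510 with an estimated correlation, and lost without CAF replicate 2, median 0.40; without CAF replicate 4 the median was 0.30). Over its alternatives the adjusted p ran from 0.00231 to 0.510, and its mean differed by 0.27 against the ls and by 0.61 against the vs normal arrays.

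Integrins, adhesion genes and sterol synthesis genes were also called by camera with no member past the test over all genes. Of 21 integrins and adhesion genes 0 passed in either adjustment. Cd44, the hyaluronan receptor, had 0.85 ± 0.23 (adjusted p = 0.0887), Alcam 0.76 ± 0.37 (adjusted p = 0.264) and Itgb8 -0.82 ± 0.34 (adjusted p = 0.196). A dim probe set of Cd44 had -0.07 ± 0.07 and 1 of Alcam -0.02 ± 0.18. Their median was 0.32 (camera adjusted p = 0.0441, lost at adjusted p = 0.510 with an estimated correlation, and lost without normal replicate 2, 3 or 4, medians 0.33, 0.18 and 0.24, or CAF replicate 1 or 2, medians 0.24 and 0.33). Over its alternatives the adjusted p ran from 0.00107 to 0.510, and its mean differed by 0.23 against the ls and by 0.32 against the vs normal arrays. Of 17 cholesterol synthesis genes 0 passed in either adjustment, with a median of 0.31 (camera adjusted p = 0.0194, lost at adjusted p = 0.803 with an estimated correlation, and lost without normal replicate 1, median 0.10, or CAF replicate 1, median 0.20). Over its alternatives the adjusted p ran from 0.00388 to 0.803, and its mean differed by 0.10 against the ls and by 0.45 against the vs normal arrays. Hsd17b7 and Nsdhl, enzymes of the later pathway, had 1.00 ± 0.28 and 0.52 ± 0.26, Idi1, an isomerase of the earlier pathway, 0.76 ± 0.40 and the regulator Srebf2 -0.23 ± 0.18, with adjusted p-values of 0.0928 to 0.488; a dim probe set of Hsd17b7 had -0.04 ± 0.07.

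Genes of cell division varied between cultures of both groups. Of 31 cell cycle genes 0 passed over all genes or adjusted over the list alone, and 30 differences were negative, with a median of -0.87 (camera adjusted p = 0.0558; adjusted p = 0.903 with an estimated correlation). The list mean was 10.18 ± 1.62 in normal and 9.37 ± 1.28 in CAF arrays and ran from 7.99 to 11.44 and from 7.26 to 10.76. Foxm1, a transcription factor of mitosis, had -0.62 ± 0.26 (adjusted p = 0.197), Ccnb2, a mitotic cyclin, -1.62 ± 1.02 (adjusted p = 0.367), the checkpoint kinase gene Bub1b -1.19 ± 0.72 (adjusted p = 0.349) and Rrm2, a ribonucleotide reductase subunit, 0.24 ± 1.05 (adjusted p = 0.912). Against the ls and the vs normal arrays Rrm2 differed by -1.41 ± 1.20 and 1.34 ± 1.05, Ccnb2 by -2.60 ± 1.32 and -0.97 ± 1.15 and Bub1b by -2.01 ± 0.91 and -0.65 ± 0.79. The list mean in CAF differed by -1.91 from the ls normal arrays and by -0.08 from the vs normal arrays. Camera called the list lower without normal replicate 1 (-1.23), normal replicate 2 (-1.41) or CAF replicate 1 (-0.93), 2 (-1.21), 4 (-0.91) or 5 (-0.93). The median was -0.54, -0.56 and -0.55 without normal replicate 3, 4 and 5 and -0.30 without CAF replicate 3, and its adjusted p ran from 8.20e-07 to 0.903 over its alternatives. Of 20 p53 targets and senescence genes 0 passed in either adjustment, with a median of 0.36 (camera adjusted p = 0.0245, lost at adjusted p = 0.660 with an estimated correlation, and lost without normal replicate 3, median 0.20, or 4, median 0.30). Over its alternatives the adjusted p ran from 0.00244 to 0.660, and its mean differed by 0.48 against the ls and by 0.22 against the vs normal arrays. The p53 regulator Mdm2 had 0.65 ± 0.18 (adjusted p = 0.0900; a dim probe set -0.04 ± 0.07), Perp, a target in cell death, 1.75 ± 0.66 (adjusted p = 0.163), Zmat3 0.63 ± 0.29 (adjusted p = 0.233) and the nuclear lamin Lmnb1 -0.91 ± 0.44 (adjusted p = 0.258).

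Markers of macrophages were bright in both groups. The lysozyme genes Lyz1 and Lyz2 read 15.06 ± 0.31 and 14.76 ± 0.51 in normal and 15.25 ± 0.16 and 15.02 ± 0.28 in CAF arrays. The Lyz1 value is from a probe set with the _x_at suffix, and its probe set without that suffix had a mean of 5.89. The bright reading may therefore not be of Lyz1 itself. Tyrobp, an adaptor of myeloid receptors, read 12.50 ± 1.68 and 12.88 ± 1.03. Of 18 macrophage markers 0 passed over all genes or adjusted over the list alone, and 17 differences were positive, with a median of 0.49 (camera adjusted p = 0.0830; adjusted p = 0.903 with an estimated correlation). Camera called the list higher without normal replicate 1 (median 0.95), normal replicate 3 (0.76) or CAF replicate 3 (0.80). The median was 0.12 and 0.27 without normal replicate 2 and 5 and 0.23 without CAF replicate 1, and its adjusted p ran from 0.00168 to 0.903 over its alternatives. The list mean differed by 1.02 between CAF and the ls normal arrays and by 0.11 between CAF and the vs normal arrays. Of 12 mesothelial markers, 1 rose, Uchl1, a deubiquitinase also found in neurons (1.86 ± 0.28, 3.62-fold, adjusted p = 0.0385; 1.65 against the ls and 1.99 against the vs normal arrays), 0 fell and 11 did not pass; adjusted over the list alone, 2 rose. The uroplakin genes Upk1b and Upk3b, bright mesothelial markers, had -0.48 ± 1.25 and -1.07 ± 1.51, and the list median was -0.46 (camera adjusted p = 0.892; -1.28 to -0.069 without 1 array). Of 8 neutrophil markers 0 passed over all genes and 1 fell adjusted over the list alone, with a median of -0.32 (adjusted p = 0.532; -0.21 without normal replicate 3, whose list mean was 10.92 against 6.54 to 7.32 on the other normal arrays). The list mean differed by 0.48 between CAF and the ls normal arrays and by -0.98 between CAF and the vs normal arrays. S100a8, Mmp8 and Camp, granule and cytosol proteins of neutrophils, had 1.51 ± 1.09, 1.09 ± 0.66 and 0.00 ± 1.03. Mmp8 differed by 2.20 ± 0.72 against the ls and by 0.35 ± 0.63 against the vs normal arrays. Of 12 pericyte and vascular muscle markers 0 passed over all genes and 1 rose adjusted over the list alone. The list median was 0.14 (camera adjusted p = 0.130), and 0.081 to 0.34 without 1 array. The muscle proteins Cnn1 and Des had 0.14 ± 0.16 and 0.14 ± 1.16. Des differed by -0.95 ± 1.52 against the ls and by 0.87 ± 1.33 against the vs normal arrays.

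Markers of other cell types were mostly dim, and none of the lists of this paragraph had a member past the test over all genes. The 14 general epithelial markers had a median of -0.17 (camera adjusted p = 0.313; -0.011 without normal replicate 3), with the keratins Krt18 and Krt8 at -0.45 ± 1.18 and -0.52 ± 0.91 and the junction gene Cldn3 at -0.15 ± 0.16, and 1 fell adjusted over the list alone. The 16 endothelial markers had a median of -0.05 (camera adjusted p = 0.432), and -0.15 to -0.015 without 1 array. The growth factor receptor Flt1 had 1.42 ± 0.63, Egfl7 -0.47 ± 0.12 and the adhesion gene Esam 0.05 ± 0.84. The 13 lymphocyte markers had a median of -0.07 (adjusted p = 0.0830), with the surface markers Cd4, Cd3e and Cd8a at -0.11 ± 0.08, -0.31 ± 0.09 and -0.27 ± 0.10. In the endothelial and lymphocyte lists 0 members passed adjusted over the list alone. The 8 Schwann and neural markers had a median of -0.14 (adjusted p = 0.609), with the myelin genes Pmp22, Cnp and Mbp at -0.13 ± 0.45, -0.13 ± 0.19 and -0.50 ± 0.40, and 1 rose adjusted over the list alone. The 12 skeletal muscle markers had a median of -0.04 and a mean of 0.07 (adjusted p = 0.532), with the muscle actin Acta1, the troponin Tnnt1 and the creatine kinase Ckm at 1.75 ± 0.69, 0.02 ± 0.13 and -0.36 ± 0.09, and 1 fell adjusted over the list alone. Acta1 differed by 0.40 ± 0.66 against the ls and by 2.64 ± 0.57 against the vs normal arrays, and Flt1 by 0.71 ± 0.81 and 1.89 ± 0.70. The dimmer probe sets of Cldn3 had the opposite sign.

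Camera called 3 dim lists of other cell types lower in CAF, with 0 members past the test over all genes. The 15 alveolar and airway markers, of which 1 fell adjusted over the list alone, had a median of -0.17 (adjusted p = 0.0245, lost at adjusted p = 0.455 with an estimated correlation; fry adjusted p = 0.0120). Their brightest members, Pdpn, Abca3 and Hopx, had 0.35 ± 0.24, 0.37 ± 0.38 and -0.31 ± 0.28. Abca3 differed by 1.04 ± 0.40 against the ls and by -0.08 ± 0.35 against the vs normal arrays. The 10 cartilage genes, of which 5 fell adjusted over the list alone, had a median of -0.20 (adjusted p = 0.0194, lost at adjusted p = 0.455 with an estimated correlation; fry adjusted p = 0.00161). The cartilage collagens Col2a1 and Col9a1 and their regulator Sox9 had -0.41 ± 0.08, -0.22 ± 0.06 and -0.15 ± 0.13. The 4 erythroid genes, of which 2 fell adjusted over the list alone, had a median of -0.24 (adjusted p = 0.0341, lost at adjusted p = 0.455 with an estimated correlation; fry adjusted p = 0.00156), with the erythroid regulator Klf1, the heme enzyme Alas2 and the anion exchanger Slc4a1 at -0.17 ± 0.11, -0.37 ± 0.20 and -0.27 ± 0.06. The median levels of these 3 lists were 6.47, 6.72 and 5.92, where genes in general had slightly lower values in CAF: ranked by level, the 3639 dimmest genes had a median difference of -0.07 and the next 3638 of -0.12. Over their alternatives the adjusted p ran from 0.0120 to 0.455 (alveolar), 0.00161 to 0.455 (cartilage) and 0.00156 to 0.455 (erythroid). Against the ls normal arrays the list means differed by -0.04, -0.26 and -0.20, and against the vs normal arrays by -0.22, -0.15 and -0.30. Without CAF replicate 2 the alveolar and erythroid calls were lost (medians -0.16 and -0.26). The 15 ribosomal proteins of the control list were all negative, with a median of -0.17. Camera called them lower (adjusted p = 0.0118, lost after quantile normalisation at a median of -0.10, lost at adjusted p = 0.798 with an estimated correlation, and 0.000703 to 0.798 over its alternatives). Without normal replicate 3 their median was -0.11. Their mean differed by -0.20 against the ls and by -0.13 against the vs normal arrays; 0 passed in either adjustment, and Rps14, Rpl10a and Rps9 had -0.24 ± 0.07, -0.27 ± 0.09 and -0.24 ± 0.10.

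The normal arrays carry label codes with different prefixes, and the 3 with prefix vs were compared with the 2 with prefix ls. Limma called 0 genes (1433 at an unadjusted p under 0.05, lowest adjusted p 0.390). The count was 2233 without normal replicate 3 and 1 without normal replicate 5. Among the lists, the mean of the cell cycle genes differed by -1.83 between the vs and the ls arrays, that of macrophage markers by 0.90 and that of the inflammatory genes by -0.16. CAF against the vs arrays gave 285 genes, 215 higher and 70 lower, and CAF against the ls arrays gave 0 (2649 at an unadjusted p under 0.05).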

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

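The gap between the array farthest from the rest of its group and its nearest neighbour was compared with the range of the group for 148 list means and named genes. In 6 cases that gap was larger than in about 95% of groups of 5 drawn from a normal distribution; chance alone gives 7.4 such cases in 148. Normal replicate 3 accounts for 3 of them. Its mean was 9.18 over the interferon-stimulated genes (7.98 to 8.27 on the other normal arrays), 8.96 over the MHC class II genes (6.70 to 7.06) and 10.92 over the neutrophil markers (6.54 to 7.32). Normal replicate 1 had a mean of 9.93 over the cholesterol synthesis genes (10.75 to 10.96 on the others). CAF replicate 4 had a mean of 10.82 over the hypoxia and glycolysis genes (10.88 to 10.90 on the others), and CAF replicate 2 read 6.49 for Apoc1 (5.85 to 5.93).

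Probe sets absent from the probe-to-gene table are outside the gene comparison. Of 9160 such probe sets, 92 differed between CAF and normal fibroblasts when probe sets were tested singly with limma (25 higher, 67 lower). Over all 45037 probe sets tested singly, 605 were called (412 higher, 193 lower).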

How the results depend on the processing

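The covariates for macrophage markers and the cell cycle and the exact permutation of list means were chosen after the results were seen, and the other settings before. The count of 137 genes rests on adjusted p-values close to the threshold and on single arrays. All 137 genes kept their direction after quantile normalisation and median centring, with the mean of all probe sets and with the macrophage, cell cycle and Y-linked covariates, and so did the 134 tested without _x_at and _s_at probe sets. Leaving out arrays cannot turn the direction of genes whose groups do not overlap. The 137 genes were selected on these same arrays. They kept their direction also with the replicate block and with the prefix term, which called 0 genes. A kept direction is therefore weak evidence of stability. Over the settings, 1053 list values led to the same call and direction, 53 gained a call, 96 lost it and 1 turned; for the named genes these were 3812, 72, 330 and 0. The values below are those that differ, and the cause was not tested. Array weights put the normal replicates 1, 2 and 3 at 0.400, 0.331 and 0.655 and the other arrays at 0.957 to 1.92. The arrays share replicate numbers without a stated pairing. With the replicate number as a replicate block, limma called 0 genes, 0 higher, 0 lower and 0 with a 2-fold difference (3017 at an unadjusted p under 0.05, lowest adjusted p 0.115). Residuals of same-numbered arrays correlated at -0.53 to 0.34, and 1 of 5 normal arrays matched its own number best.

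The count of genes (higher, lower, at least 2-fold) was 46 (36, 10, 23) with an intensity trend and robust prior, 41 (37, 4, 23) with a filter at a mean of 7, 90 (41, 49, 23) after quantile normalisation, of which 65 are among the 137, and 16 (12, 4, 8) after median centring. It was 605 (412, 193, 122) with all probe sets tested singly, 1597 (983, 614, 206) with array weights, 456 (349, 107, 115) with the macrophage covariate and 398 (242, 156, 68) with the cell cycle covariate. With the Y-linked level as covariate 92 were called, 18 of them lower. On the ls arrays alone limma called 1 gene (1, 0, 1; 4848 at an unadjusted p under 0.05). With the label prefix as a term it called 0 (0, 0, 0; 2649), and the exact Wilcoxon test, whose smallest possible p the 137 genes already have, called 0 (0, 0, 0; 3184). Without 1 array the count ran from 0 to 166, higher from 0 to 142, lower from 0 to 33, 2-fold from 0 to 63, and that between the prefixes of normal arrays from 0 to 2233. The number of lists called was 0 with an estimated correlation, 0 by exact permutation, 3 by fry, 7 with the cell cycle covariate, 5 with the filter at 7 and 8 to 16 without 1 array.

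List medians that go with a changed call are these. With camera at an estimated correlation, and by exact permutation, the 12 called lists lost their call at unchanged medians: contractile 0.14, TGF-beta 0.20, inflammatory 1.06, RAS-MAPK 0.45, immediate early 0.46, p53 0.36, cholesterol 0.31, integrins 0.32, ribosomal -0.17, alveolar -0.17, cartilage -0.20 and erythroid -0.24. Fry ended the same calls except those of the alveolar, cartilage and erythroid lists. The filter at 7 ended the calls of the contractile (0.14), TGF-beta (0.20), RAS-MAPK (0.45), immediate early (0.48), p53 (0.36), cholesterol (0.31), integrin (0.32) and alveolar (-0.20) lists and gave calls of cell cycle (-0.88) and interferon (-0.32) genes. The filter at 5 ended those of the contractile (0.14) and integrin (0.32) lists.

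With the ls arrays alone and with the prefix as a term alike, the contractile (0.12), RAS-MAPK (0.24), immediate early (0.30), cholesterol (0.093), integrin (0.18), alveolar (-0.15) and erythroid (-0.22) lists lost their call. The interleukin-6 family (0.53), cell cycle (-2.05), MHC class I (0.39) and macrophage (1.06) lists gained it. The prefix term alone ended that of TGF-beta (0.23), and the ls arrays alone gave calls of growth factors (0.23), NRF2 (0.29) and, turned upward, hypoxia (0.17). Array weights ended the calls of the contractile (0.12), cholesterol (0.20), integrin (0.25), alveolar (-0.16) and erythroid (-0.24) lists and gave those of interleukin-6 family (0.60), cell cycle (-1.56) and macrophage (0.89) lists.

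Quantile normalisation ended the calls of p53 (0.28), ribosomal (-0.10), alveolar (-0.13) and erythroid (-0.17) lists and gave those of cell cycle (-0.95) and interferon (-0.26) genes. Median centring gave calls of interleukin-6 family (0.30), growth factor (0.076) and macrophage (0.42) lists. The mean of all probe sets ended those of contractile (0.084) and erythroid (-0.19) lists. Probe sets tested singly ended that of erythroid genes (-0.19) and gave those of cell cycle (-0.58), interferon (-0.23), MHC class II (-0.63), NRF2 (0.31), macrophage (0.43) and interleukin-6 family lists (-0.031, with camera pointing up). The replicate block gave calls of interferon (-0.31) and macrophage (0.49) lists, leaving out _x_at and _s_at probe sets that of interferon genes (-0.31), and the Y-linked covariate that of cell cycle genes (-0.85). The macrophage covariate ended the integrin call (0.37) and gave those of cell cycle (-1.0) and interferon (-0.30) genes. The cell cycle covariate ended those of contractile (0.11), TGF-beta (0.15), p53 (0.20), integrin (0.20) and erythroid (-0.25) lists.

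Without 1 array, medians of lists whose call changed ran from 0.16 to 0.56 (interleukin-6 family), 0.057 to 0.26 (growth factors), -1.41 to -0.30 (cell cycle), -0.36 to -0.091 (interferon), 0.10 to 0.37 (cholesterol), 0.12 to 0.95 (macrophage), 0.064 to 0.24 (contractile), 0.21 to 0.44 (NRF2), 0.18 to 0.41 (integrins), -0.39 to -0.049 (collagens), 0.11 to 0.29 (TGF-beta), 0.20 to 0.52 (p53), 0.30 to 0.53 (immediate early), -0.19 to -0.14 (alveolar) and -0.26 to -0.22 (erythroid). The inflammatory list was called without each array in turn, at 0.87 to 1.34. Adjusted p-values over the 26 alternatives ran from 0.0132 to 0.292 for Csf3, 0.0199 to 0.306 for Il1a, 0.0123 to 0.292 for Lif, 0.0274 to 0.306 for Clcf1 and 0.0324 to 0.351 for Il6, with 17, 11, 14, 9 and 2 under the threshold.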

Other observations

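The tests of the macrophage, label prefix and cell cycle explanations below, singly and together, and the correlation of the macrophage markers were chosen after the results were seen; those of the chemosensory genes and of the other splits were written before. Lists of immune and stress genes that the text has not yet described had 0 members past the limma test over all genes. Of 25 interferon-stimulated genes 22 had negative differences, with a median of -0.31 (camera adjusted p = 0.0558), and 1 fell adjusted over the list alone, Irf1, a transcription factor of the interferon response (-0.45 ± 0.10, adjusted p over all genes = 0.0676). The antiviral genes Oas3 and Oas2 had -0.33 ± 0.12 and -0.31 ± 0.11, and Ifit2 had 0.55 ± 0.23. The list was called lower without normal replicate 1 (-0.27), 4 (-0.35) or 5 (-0.35) or CAF replicate 3 (-0.36) or 4 (-0.30), and its median was -0.091 without normal replicate 3. The list mean differed by 0.069 between CAF and the ls normal arrays and by -0.45 between CAF and the vs normal arrays. The 11 genes of MHC class I had a median of 0.06 (adjusted p = 0.897; -0.12 to 0.084 without 1 array, and 0.39 against the ls and -0.18 against the vs normal arrays), with Psme1 at -0.32 ± 0.19, Psmb8 at -0.89 ± 0.57 and Tap2 at 0.28 ± 0.18, and the 6 of MHC class II a median of -0.80 (adjusted p = 0.215; -0.21 without normal replicate 3), with Ciita, their regulator, at -0.12 ± 0.06, H2-Eb1 at -0.79 ± 0.42, H2-Aa at -0.82 ± 0.46 and H2-DMa at 0.14 ± 0.31 (0.75 ± 0.29 against the ls and -0.26 ± 0.26 against the vs normal arrays). The 12 complement genes had a median of 0.12 (adjusted p = 0.897; -0.15 to 0.40 without 1 array, and 0.74 against the ls and -0.22 against the vs normal arrays), with Cd55, a surface inhibitor of complement, at 2.42 ± 0.71 (adjusted p = 0.103), C2 at -0.78 ± 0.31 and C1s1 at -0.68 ± 0.38. In these 3 lists 0 members passed adjusted over the list alone. Of 22 hypoxia and glycolysis genes, with a median of -0.04 (adjusted p = 0.892; 0.17 against the ls and -0.13 against the vs normal arrays), 1 rose and 2 fell adjusted over the list alone; Hk2, a hexokinase, had 0.85 ± 0.17 (adjusted p over all genes = 0.0534), the glycolytic enzyme gene Tpi1 -0.58 ± 0.13 (0.0676) and the lactate transporter Slc16a3 -1.47 ± 0.43 (0.102; -0.68 ± 0.44 against the ls and -2.0 ± 0.38 against the vs normal arrays). The 17 NRF2 and oxidative stress genes had a median of 0.33 (adjusted p = 0.130; called without normal replicate 2, 0.44, and 0.21 without normal replicate 1), with Gclc, of glutathione synthesis, at 0.60 ± 0.18, Gsr at -0.59 ± 0.18 and Gstp1 at -0.29 ± 0.08. The 18 genes of the unfolded protein response had a median of -0.02 (adjusted p = 0.776, camera pointing up; -0.088 to 0.044 without 1 array), with Dnajb9 at 0.34 ± 0.20, Atf3 at 0.48 ± 0.28 and Pdia6 at -0.30 ± 0.19. In these 2 lists 0 members passed adjusted over the list alone.

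Developmental pathways and genes of fibroblast identity had no member past the limma test over all genes either. The 10 hedgehog genes had a median of -0.15 (camera adjusted p = 0.609), and 1 rose adjusted over the list alone, Ptch1, the receptor and a target of the pathway (1.48 ± 0.36, adjusted p over all genes = 0.0724; a dim probe set -0.16 ± 0.07); the co-receptors Gas1 and Cdon had -1.47 ± 0.49 and -0.34 ± 0.13. The 13 Notch genes had a median of -0.07 (camera adjusted p = 0.692), and -0.13 to 0.0077 without 1 array. Adjusted over the list alone 1 fell, the ligand Jag2 (-0.26 ± 0.06). The ligands Dll4 and Dll1 had -0.31 ± 0.10 and 0.58 ± 0.22, and Nrarp had -0.20 ± 0.07. The 25 genes of lung fibroblast identity had a median of -0.11 (adjusted p = 0.609) and 0 members past adjustment over the list alone, with the homeobox gene Meox1 at -0.37 ± 0.10 (adjusted p = 0.0829), Npnt, nephronectin, at 1.02 ± 0.36 and Gpc3, a glypican, at -2.02 ± 0.75. The 15 adventitial genes had a median of -0.15 (adjusted p = 0.692; -0.33 to -0.051 without 1 array), and 1 fell adjusted over the list alone, Adh7 (-0.30 ± 0.07); Sema3c and Cd34 had 0.95 ± 0.30 and -1.09 ± 0.42, and Cd34 differed by -0.42 ± 0.47 against the ls and by -1.53 ± 0.41 against the vs normal arrays. The 14 lipofibroblast genes had a median of 0.15 (adjusted p = 0.337; 0.021 to 0.18 without 1 array) and 0 members past adjustment over the list alone, with the lipid droplet genes Plin2 and Plin4 at 0.63 ± 0.23 and -0.17 ± 0.07 and the growth factor Fgf10 at 1.26 ± 0.52.

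The inflammatory list mean was 1.23 higher in CAF, and a macrophage share that differs between cultures, the label prefix or the state of the cell cycle could each have given such a difference. With the macrophage marker mean as a covariate the difference was 1.225 (95% confidence interval 0.446 to 2.00) and with the cell cycle mean 1.307 (0.546 to 2.07). Against the normal arrays with prefix ls alone it was 1.131 (0.137 to 2.13). Each interval lies above 0, which for the macrophage and cell cycle means argues against that explanation alone as the whole cause. For the prefix the argument is weak, since its interval rests on 2 ls normal arrays and a residual spread pooled over all 10 arrays. In the comparison with the ls normal arrays, however, the macrophage list mean was higher in CAF by 1.02 and the cell cycle list mean lower by 1.91. In joint models the difference was 1.32 (0.432 to 2.21) with both means, 1.31 (0.043 to 2.59) with prefix and cell cycle, 1.10 (-0.095 to 2.29) with prefix and macrophage mean and 1.38 (-0.41 to 3.17) with all 3; the last 2 intervals include 0, so these explanations together stay open. The age and housing of the mice are not given in the sources used here, and their effect was not tested.

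Dim genes had lower values in CAF, which could come from an array-wide shift of low signals rather than from the cells. Chemosensory receptor genes, which fibroblasts are not known to use, served as a test: the median of 73 such genes was -0.08231, 63 were negative (exact permutation p = 0.0159), and the other 7205 dim genes had a median of -0.09. After quantile normalisation the chemosensory median was -0.029. The values go with the array-wide shift, and small decreases of dim genes, among them the alveolar, cartilage and erythroid lists, may share it. Of the 73, Vmn1r148 and Olfr701 are among the 35 genes called lower. At the bright end, the 3639 brightest genes had a median difference of 0.07 and the 3638 next below 0.11. After quantile normalisation these medians were 0.02 and -0.01. The 3639 genes in the middle by level went from -0.04 to -0.12, and the 3639 dimmest and the next 3638 then had -0.01 and -0.07. A difference with level thus remained after quantile normalisation. Small increases of bright lists may share a shift of scale too, among them the contractile, TGF-beta and cholesterol lists (median levels 13.85, 11.5 and 10.87). This was not tested.

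Macrophage markers varied together between cultures of the same group, with a mean pairwise correlation around the group means of 0.8891, against at most 0.587 in 10000 random lists matched on level and spread (p = 1e-04, the smallest they can give). The Spearman value was 0.914, that without the 2 arrays farthest from the median (normal replicates 1 and 2) 0.883, and that within the 7 ls arrays 0.861. Lyz2 ran from 14.24 to 15.39, Tyrobp from 10.37 to 14.25, Cd68 from 9.66 to 13.08 and Adgre1 from 7.84 to 11.94, and 0 of the 18 markers are in another list. Other lists also lay above the highest random list by the same measure: cell cycle at 0.945, ribosomal proteins at 0.723 and cholesterol synthesis at 0.670. The random lists therefore cannot tell a differing share of macrophages from genes that are regulated together. A share of macrophages that differs between cultures is a candidate explanation, as a hypothesis. No sort that would remove them is described in the labels, and a shared regulation of these genes within fibroblasts was not tested.

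Of the 126 ways to split the 10 arrays into 5 and 5, 100 were drawn, the real one included. A count as large as the real 137 genes came from 1 of the 100, the real split itself, and the highest count of another split was 2. Chance assignment of the arrays is therefore unlikely as the source of the count, but not excluded. The smallest share that the draw can give is 1 of 100. These splits exchange arrays across the label prefix and exclude nothing about it: with the prefix as a term, which compares CAF with the ls normal arrays, limma called 0 genes (2649 at an unadjusted p under 0.05), and CAF against the vs normal arrays gave 285. The same holds for the 41 genes with a 2-fold difference: 1 of the 100, with 2 as the highest other. For the 12 lists called by camera with the preset correlation, 39 of the 100 splits gave as many, and the highest other was 19, so chance cannot be excluded for that count. Camera with an estimated correlation called 0 lists and fry called 3. The exact permutation test also called 0, with 10 lists at an unadjusted p under 0.05, and its p was the smallest possible, 0.00794, for the inflammatory, interleukin-6 family, cartilage and erythroid lists.

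Upk3b, a mesothelial gene chosen after its values were seen, ran from 5.35 (normal replicate 2) to 14.03 (normal replicate 1), a range of 8.69 on the log2 scale. Ngp, a neutrophil granule gene also chosen after its values were seen, read 12.29 on normal replicate 3 and 5.38 to 6.27 on the other arrays.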
